A study of Mus musculus with 18 samples.

How the data were processed

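The series holds HEAP libraries, a form of CLIP-seq in which Argonaute 2 (Ago2) fused to a Halo tag is pulled down after UV crosslinking and digested, so that the miRNAs and RNA fragments it held can be sequenced. Per the labels' protocols, the distal colon of C57BL/6 mice aged 8 to 12 weeks was scraped to enrich for epithelium, minced, and crosslinked 3 times at 400 mJ per square centimetre before freezing and lysis. There were 18 libraries in 6 groups of 3: miRNA, pulldown mRNA and input control libraries, each from mice with wild-type K-Ras (WT) and from mice with 1 oncogenic K-Ras-G12D allele (G12D), both carrying Halo-Ago2 and Fabp-Cre. The 6 input control libraries were not analysed here, so the planned comparison of pulldown against input was not made, and a change in a peak cannot be separated from a change in its transcript. The labels give replicate numbers but do not say that each library came from its own mouse, so p-values of tests between libraries measure the spread between these libraries.

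STAR 2.5.2b and DESeq2 are named in the submitters' processing notes, with the builds mm10 and GRCm38. The peak caller, the counting rules and the features behind the size factors are not given in the sources used here. Both deposited tables of normalized values hold a signal that is never negative: reads per mature miRNA, or per merged peak, divided by 1 factor per library. The low values of each library were whole multiples of 1 step, and with that step 100.0% of the values above 0 in each of the 12 analysed libraries came out as whole reads within 0.01 of a read. The deposited differential tables give the authors' log2 fold changes with their standard errors, and the authors' p-values and adjusted p-values, per the file headers. The deposited peak lists, 1 per genotype and 1 merged, carry the authors' score for each peak, whose lowest value was 1.30 in both genotype lists and 0 throughout the merged list; whether libraries were pooled for calling is not stated. The score was used only to rank peaks within a list. Annotation class, gene label and miRNA seed matches of each peak are the authors', per the file headers, and the asterisk on some classes is not explained there. The peak columns carry the genotype code and replicate number of the labels and were taken as the pulldown mRNA libraries. All coordinates are GRCm38, counted from 1.

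The main test was limma on log2(normalized reads + 1) with a variance trend, for G12D against WT within each table, with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. A fold change on this scale understates the change of features with low values. The miRNA test used features with a mean of at least 10 normalized reads over the 6 libraries, and the peak test those with a mean of at least 5. This left 254 of 459 miRNAs and 4438 of 5554 peaks. Sets were tested with limma's camera at a preset correlation of 0.01, beside a version with an estimated correlation, and adjusted over the sets of 1 kind. These comprised 15 miRNA lists, 10 gene lists and 42 seed families, all chosen before the data were examined. A miRNA or gene list needed 3 tested members and a seed family 10 tested peaks with a 7-mer or longer match to nucleotides 2 to 8. Of the 42 families 27 could be matched by name to the families of the peak annotation. Annotation classes were compared with Fisher's exact test, two-sided, in which peaks are not independent replicates. Shares of reads per library carry Wilson 95% intervals, and groups of libraries were compared with an exact permutation test, whose smallest possible p at 3 against 3 is 0.1. Intervals and floors cover counting error only. A group with 0 reads was set to a floor of 3 counts over the group.

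The miRNAs and peaks named in the text were fixed by rule before the data were examined. The rule took features past the threshold whose 3 G12D libraries all lay on one side of the 3 WT libraries, and of these the 10 with the largest log2 fold change in each direction. It added the 5 with the highest mean and up to 4 members per list with the highest mean, of which the first 2 were used; that lower number was set after the data were seen, for length. A peak was named by its gene, or by its position where it had none. The counts of all peaks of a named gene, and the values of other called peaks of Smad7, Acvr1b and Cdc34, were added after the data were seen. A further peak chosen that way is not reported here. Alternatives covered the pseudocount, the filter, the scaling (same total per library, quantile normalization), the replicate number as a block, the variance trend, each library left out in turn, and edgeR's quasi-likelihood test and DESeq2 on the recovered reads. Alternatives added after the data were seen were thinning to the shallowest library, peaks called in both genotype lists, peaks outside rRNA and snRNA, 3' UTR peaks, leaving out both libraries numbered 2, and edgeR with the deposited factors. The latter called 42 miRNAs and 2273 peaks.

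The scripts were tested on simulated counts drawn from the real means, factors and dispersions. For the 254 miRNAs of G12D against WT, limma recovered 41.2% of 17 changes of 1 log2 unit and 95.7% of 23 changes of 2 log2 units, with 2 false calls among 184 unchanged miRNAs. For the 4438 peaks it recovered 0% of 96 changes of 1 log2 unit and 25% of 104 changes of 2 log2 units, with 0 false calls among 4208. Far more peaks were called in the data than were changed in the simulation, which eases the adjustment. These shares may therefore understate the recovery in the data. A missing call was still not read as no change of a single peak. Replicates within a group differed by more than sampling noise in every pair, by a chi-square test of their counts. The analysis used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.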

Results

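To see which miRNAs and which RNA sites Ago2 holds in the colonic epithelium, and how this differs when oncogenic K-Ras is present, HEAP libraries were compared between WT and G12D mice. Each genotype had 3 miRNA libraries and 3 pulldown mRNA libraries. The miRNA libraries held 437439, 535932 and 466178 reads in WT and 337788, 388247 and 433245 reads in G12D. Pulldown depth was less even: the WT libraries held 100978, 54401 and 148770 reads in merged peaks, and the G12D libraries 148927, 723937 and 247358. Between 1294 and 1854 of the 5554 merged peaks had 0 reads in a WT library, against at most 177 in a G12D library. Below, the p-values of tests between libraries measure the spread between these libraries.

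The 5 miRNAs with the highest mean over all 6 libraries were miR-21a-5p, miR-194-5p, miR-200c-3p, miR-27a-3p and miR-30e-5p. miR-21a-5p, widely known as an oncogenic miRNA, rose from 22676 ± 3202 to 37519 ± 2513 normalized reads (SD, n = 3 per genotype; log2 fold change 0.73 ± 0.16 SE, limma adjusted p = 0.00159). miR-27a-3p rose 2.08-fold, from 12984 ± 4530 to 26942 ± 1743 normalized reads (limma adjusted p = 5.57e-05). miR-194-5p, an intestinal epithelial miRNA, passed more narrowly at a log2 fold change of 0.53 (limma adjusted p = 0.0339), and its groups overlapped. miR-200c-3p and miR-30e-5p did not pass, at 0.25 ± 0.17 and 0.26 ± 0.18. Of the 254 miRNAs tested, limma called 40 changed, 23 higher and 17 lower in G12D. In 36 of them the 3 G12D libraries lay on one side of the 3 WT libraries, an arrangement that chance gives in 10% of miRNAs and that 75 of the 254 showed. The authors' deposited table holds 30 miRNA calls, 14 higher and 16 lower, of which 26 were among the 40, all in the same direction.

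Among the 10 named miRNAs that rose most, miR-1247-5p was the farthest, from 23.9 ± 13.7 to 182 ± 94.0 normalized reads (log2 fold change 2.92 ± 0.44 SE, limma adjusted p = 7.83e-06). miR-205-5p was the most abundant of them and rose from 1587 ± 321 to 3569 ± 902 normalized reads (1.16 ± 0.25, limma adjusted p = 0.00123). miR-130b-5p, miR-340-3p, miR-690, miR-151-5p, miR-3068-5p, miR-17-3p, miR-9-5p and miR-652-5p also rose, with log2 fold changes of 2.42 down to 1.26, all from means under 70 normalized reads in either group. The 10 that fell most were led by miR-5107-5p, which fell by 2.76 ± 0.53 SE on the log2 scale, from a mean of 27.7 to 4.91 normalized reads (limma adjusted p = 0.000334). The related miR-99b-5p and miR-99a-5p fell by 1.91 and 1.38, and miR-127-3p and miR-136-5p fell by 1.70 and 1.39. miR-500-5p, miR-673-5p, miR-194-1-3p, miR-137-3p and miR-5114 fell by 1.51 to 1.84. Of the 40 calls, 20 ended without WT replicate 3, among them those of miR-194-5p, miR-192-5p and miR-200b-3p, and 16 without G12D replicate 2.

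The balance of the miRNA calls rested on the scaling. With each library rescaled to the same total, the median tested miRNA moved from 0.11 to -0.26, and the 37 calls split into 6 higher and 31 lower. edgeR with TMM gave 11 higher and 26 lower, DESeq2 13 and 21, and quantile normalization 19 and 21. None of the 40 miRNAs changed sign under any alternative, and miR-1247-5p, miR-205-5p, miR-5107-5p, miR-99b-5p, miR-500-5p and miR-673-5p passed under all that tested them. The call of miR-21a-5p ended with quantile normalization, where its log2 fold change was 0.07, and without the variance trend (limma adjusted p = 0.105). With the same total per library it was 0.37 and still passed (limma adjusted p = 0.015).

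**Figure D1:**
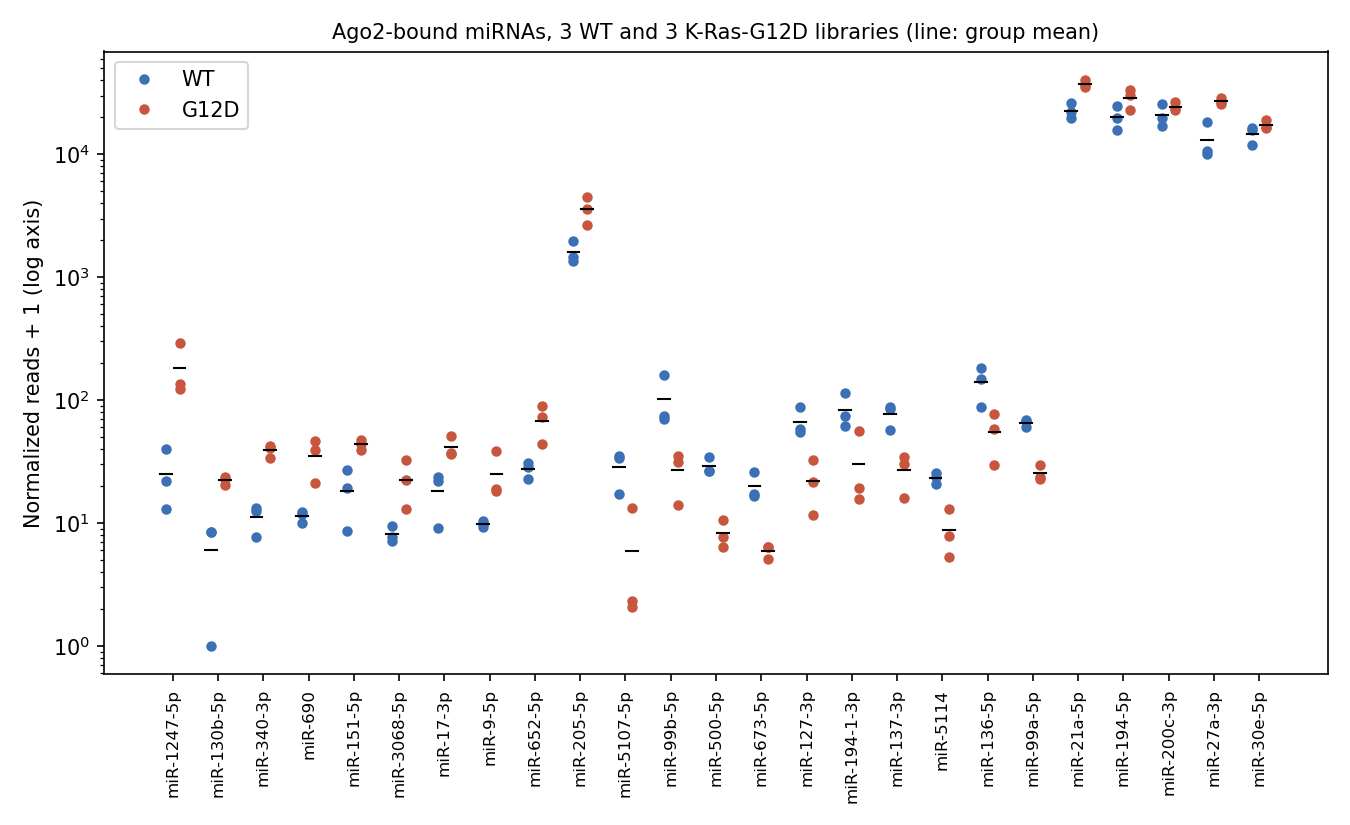
Normalized reads plus 1 on a log axis for the named miRNAs with the largest changes and the highest means, with a point per library (WT blue, G12D red, 3 each) and a line at each group mean. miR-1247-5p stands at a mean of 23.9 in WT and 182 in G12D, and miR-5107-5p at 27.7 and 4.91.

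No miRNA list passed as a whole: camera called 0 of 14, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.117. With no filter on low values it called 3, the miR-200, miR-30 and miR-23 clusters lists (adjusted p = 0.0307; adjusted p = 0.472 or higher with an estimated correlation). The miR-200 family, which maintains epithelial identity, had a median log2 fold change of 0.36 over its 5 members. Of these miR-200b-3p passed (0.56 ± 0.19, limma adjusted p = 0.0364), and 2 members passed when adjusted over the list alone. Without WT replicate 1 the family passed (camera adjusted p = 0.00331; adjusted p = 0.521 with an estimated correlation). Its median was then 0.63, with 3 members higher and 5 adjusted over the list alone. No camera call of any list, here or below, held with an estimated correlation. The intestinal list of miR-192, miR-194 and miR-215 had a median of 0.51, and miR-192-5p (0.51, limma adjusted p = 0.0491) and miR-194-5p were the 2 of its 3 members that rose, as they did adjusted over the list alone. The miR-30 family (median 0.39) and the miR-23/27/24 clusters (0.24) had 1 of 5 members higher each, and 2 each adjusted over the list alone. In the family of miR-34 and miR-449 the median was -1.20 over 3 members: miR-449a-5p fell by 1.27 (limma adjusted p = 0.0383; 2 lower adjusted over the list alone), while the far more abundant miR-34a-5p was at -0.20 and did not pass. Of the 9 tested RAS-responsive oncomiRs, miR-21a-5p and the hypoxia-induced miR-210-3p rose, the latter from 4456 ± 430 to 8071 ± 794 normalized reads (limma adjusted p = 0.00321). Adjusted over the list alone, 3 of these oncomiRs were higher and 1 lower. The miR-17~92 list had a median of 0.42, with miR-92a-3p higher (0.61, limma adjusted p = 0.0364) and miR-19b-3p at 0.46 without passing; adjusted over the list alone 0 passed. Within the let-7, miR-15/16, miR-29 and miR-148 lists 0 members passed, over all tested or adjusted over the list alone, at medians of 0.20, 0.34, 0.37 and -0.41. let-7b-5p stood at 4320 ± 931 and 4318 ± 1034 normalized reads. The miR-26 family had too few members for the test, and miR-26a-5p in it rose from 12435 ± 1244 to 18978 ± 1411 normalized reads (limma adjusted p = 0.0143). With the same total per library, the medians of the let-7, miR-200, miR-15/16, miR-23/27/24 and RAS-responsive lists and of the neural list became negative, at or below -0.000774. That scaling also ended the calls of miR-26a-5p, miR-92a-3p, miR-192-5p, miR-194-5p, miR-200b-3p and miR-210-3p. With quantile normalization the medians of the miR-200 and miR-23/27/24 lists likewise turned negative (-0.13 and -0.02). Those of the intestinal and miR-30 lists fell to 0.013 and 0.0075.

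Markers of other cell types that a scrape can hold were also tested. Smooth muscle and stromal miRNAs had a median of -0.10 over 3 tested members, with 0 called over all tested or adjusted over the list alone. miR-133a-3p stood at 133 ± 108 and 122 ± 35.5 normalized reads and miR-143-3p at means of 56.0 and 41.7. Blood cell and endothelial miRNAs had a median of -0.14, 0 called and 1 lower adjusted over the list alone, with miR-146a-5p at -0.75 (limma adjusted p = 0.0526) and miR-142a-3p at 0.65 (limma adjusted p = 0.102); the list's mean lay above that of the other miRNAs while its median and camera pointed down. The neural and enteroendocrine list had a median of 0.35; 1 of its 5 members passed, miR-9-5p, also adjusted over the list alone, while miR-375-3p and miR-7a-5p did not, at 0.35 and -0.22. None of the 32 stromal, muscle and blood cell genes had a peak, against 37 of 42 colonocyte and goblet cell genes.

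The authors' lists held 1283 Ago2 peaks in WT and 5109 in G12D, with median widths of 50 and 56 bases. By at least 1 shared base on the same strand, 838 WT peaks overlapped a G12D peak (65.3%, Wilson 95% interval 62.7 to 67.9%), while 834 G12D peaks overlapped a WT peak (16.3%, 15.3 to 17.4%). These lists have no replicates. Of the 5554 merged peaks, 834 were in both lists, 445 only in the WT list and 4275 only in the G12D list. An annotation was given for 5448, of which 2982 were in 3' UTRs, the usual site of miRNA action, 1710 in other exons, 443 in introns and 165 in 5' UTRs. A 7-mer or longer seed match to a listed miRNA family, defined as for the seed families above, was present in 3255. Any 7-mer match that does not cover every nucleotide of that definition was not part of this count.

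Reads in merged peaks were then divided by class of RNA. Peaks in 3' UTRs took 26.9% ± 2.71 of the reads in WT and 39.6% ± 4.38 in G12D (SD, n = 3 per genotype; exact permutation p = 0.1, the smallest possible). In normalized reads these peaks held 50213 ± 6055 and 64307 ± 4679. Shares depend on which peaks were called: those only in the G12D list took 13.7% ± 1.25 in WT and 44.2% ± 4.94 in G12D. Small nuclear RNA peaks took 2.65% ± 0.581 in WT and 0.184% ± 0.0233 in G12D, and peaks at 5S and related rRNA genes 2.16% ± 0.933 and 0.565% ± 0.239 (exact permutation p = 0.1 for each). These genes have near-identical copies, so reads can be shared among their 38 peaks. The highest peak, at an rRNA locus on chromosome 17 (39847480 to 39847543), took 24.5% ± 3.84 in WT and 14.6% ± 7.07 in G12D, with overlapping groups (exact permutation p = 0.2).

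**Figure D2:**
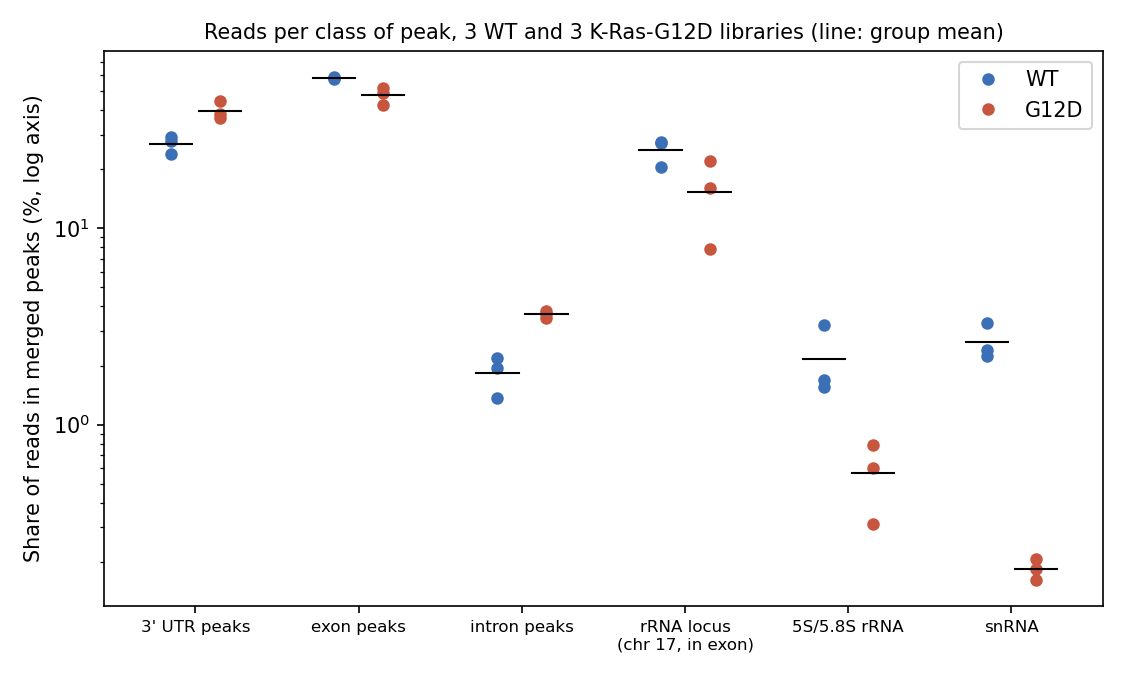
Percent of the reads in merged peaks, on a log axis, by class of peak. Each library is a point (WT blue, G12D red, 3 each), with a line at each group mean. The rRNA locus is part of the exon class, which also holds the snRNA and 5S rRNA peaks annotated as exon. Small nuclear RNA stands at a mean of 2.65% in WT and 0.184% in G12D.

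limma called 2170 of the 4438 tested peaks changed, 1607 higher and 563 lower in G12D, around a median log2 fold change of 1.05. The direction followed the list a peak was called in. Each list holds peaks called in its own genotype, so this direction was in part set by the choice of peaks. Among peaks only in the G12D list, 1489 of 3166 were higher and 21 lower (median 1.68). Those only in the WT list had 3 higher and 330 lower of 444 (median -2.81). The 828 tested peaks present in both lists, by contrast, had 105 higher and 207 lower when tested by themselves (median -0.45). The split also moved with scaling: quantile normalization gave 873 higher and 802 lower (median 0.16), edgeR with TMM 1093 and 894 (0.47), and DESeq2 1130 and 771 (0.66). Among the 1329 peaks with a mean of at least 20 it was 429 higher and 361 lower (0.13). Without G12D replicate 2, the deepest library, 1410 peaks passed, 977 of them higher. The counts were close to this without G12D replicate 3 (1451, 988 higher) and somewhat larger without G12D replicate 1 (1579, 1139 higher). The authors' deposited table holds 2726 calls, 2088 higher and 638 lower.

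**Figure D3:**
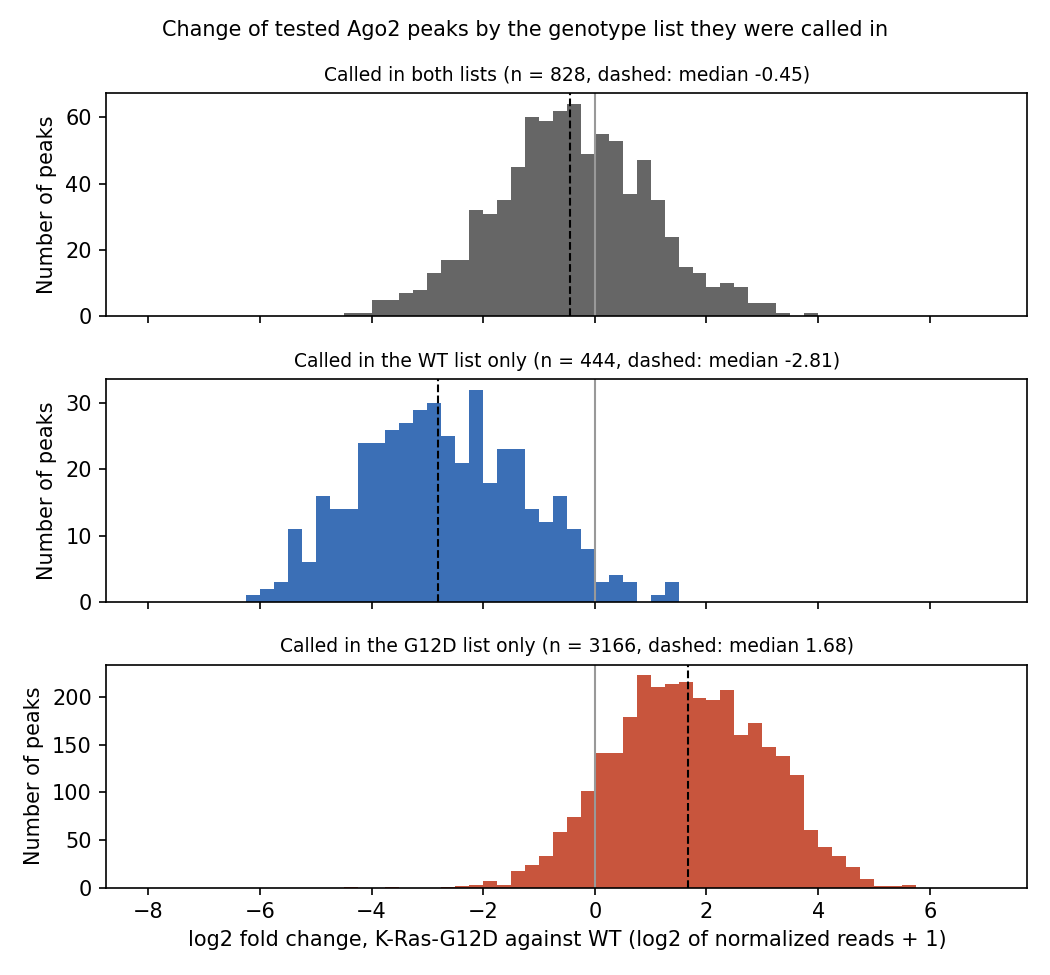
Histograms of the log2 fold change of tested peaks, G12D against WT, on the log2(normalized reads + 1) scale, with the number of peaks on the vertical axis and a dashed line at the median. The medians are -0.45 for the 828 peaks in both lists, -2.81 for those only in the WT list and 1.68 for those only in the G12D list.

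The peaks that rose most were all called only in the G12D list. A 3' UTR peak of Dhrs9, a retinol dehydrogenase gene (chromosome 2, 69402049 to 69402102), with a miR-194 site, had 2 reads in WT and 565 in G12D, a 62.8-fold difference (95% counting interval 17.3 to 520). Peaks in Hint1 (5' UTR, chromosome 11, 54866475 to 54866528) and in an intron of Nr3c2, the mineralocorticoid receptor gene (chromosome 8, 77032489 to 77032550), had 0 reads in WT and were at least 22.4-fold and 26.4-fold higher. A Rab35 exon peak (chromosome 5, 115640073 to 115640118) rose from 10.9 ± 3.39 to 392 ± 73.7 normalized reads (5.06 ± 0.36 SE, limma adjusted p = 2.09e-05). 3' UTR peaks of Ndufa4, Ivns1abp and Dstn, exon peaks of Cept1 and Muc2 and an intron peak of Upf1 rose by log2 fold changes of 4.93 to 5.32. All 10 passed under every alternative that tested them. Each name stands for 1 peak: of 10 tested peaks of Nr3c2 8 were higher and 1 lower, and of 6 of Dstn 3 were higher and 1 lower.

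The peaks that fell most were called only in the WT list in the authors' lists. They comprised the snRNA genes Gm25587 and Gm23511, the 5S rRNA genes n-R5s65 and n-R5s60, and a peak shared by Gm25555 and Zfp811. The Gm25587 peak (chromosome 10, 105040377 to 105040424) fell by 6.15 on the log2 scale, from 189 ± 29.3 to 1.69 ± 0.428 normalized reads (limma adjusted p = 2.09e-05). Others were a peak at Adcy6, a peak at RP23-468D17.1, and peaks with no gene on chromosomes 7 (112480145 to 112480201), 9 (56588241 to 56588297) and 10 (118828000 to 118828049). Of these the chromosome 7 peak had 141 reads in WT and 0 in G12D, at least 211-fold lower. Among the 5 peaks with the highest mean, that of Lypd8, which encodes a secreted antibacterial protein of the colon (5' UTR, chromosome 11, 58379051 to 58379101), fell from 6004 ± 1249 to 543 ± 141 normalized reads (limma adjusted p = 0.000269); of its 11 tested peaks 2 were higher and 4 lower. A peak with no gene on chromosome 18 (54698903 to 54698950) fell from 5856 ± 2802 to 282 ± 176. Actb (-0.44 ± 0.46) and the chromosome 17 rRNA locus (-1.06 ± 1.03) did not pass. The sign for this Actb peak turned with quantile normalization, where it passed as higher (0.48, limma adjusted p = 0.0496), while edgeR with TMM gave -0.98. Of the 12 tested Actb peaks 6 were higher and 1 lower.

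Whether changed peaks lie in 3' UTRs as often as other peaks was tested among tested peaks with an annotation. Of the lower peaks 31.4% (163 of 519) were in 3' UTRs, against 59.0% (1328 of 2249) of those not called (odds ratio 0.318, Fisher's exact two-sided p = 4.24e-30). Higher peaks were close to the latter at 56.9% (902 of 1585; odds ratio 0.916, Fisher's exact p = 0.195). With the calls of the authors' deposited table this second comparison passed, at 55.2% against 60.0% (Fisher's exact p = 0.00103). Classes outside 3' UTRs were not alike. Of 275 tested intron peaks 180 were higher and 49 lower (median 2.70). Exon peaks had 412 higher and 267 lower of 1438 (median 0.61), and 3' UTR peaks 902 and 163 of 2393 (1.23). Within peaks called in both lists, lower peaks were in 3' UTRs in 45.3% and those not called in 56.9% (Fisher's exact p = 0.00599). Peaks are not independent replicates, so these p-values are not evidence from replicate libraries.

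No gene list stood apart from the other peaks: camera called 0 of 9, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.609. All 9 medians were positive, between 0.72 and 1.90, as was that of all peaks. Peaks of 1 gene are not independent, and several lists rested on few genes. Genes with a tested peak numbered 36 for colonocyte, 20 for RAS-MAPK, 14 for miRNA machinery and 13 for PI3K genes. They numbered 12 for apoptosis, 10 for classical targets, 9 for WNT, 8 for cell cycle and 7 for TGF-beta genes. Among the 214 peaks of colonocyte and goblet cell genes 99 rose and 24 fell (median 1.38). Muc2 had 13 of its 19 tested peaks higher, and Muc3 13 of 15. The highest peak of Muc2, the main colonic mucin (exon, chromosome 7, 141691356 to 141691406, with a let-7 site), rose from 241 ± 122 to 2209 ± 627 normalized reads (3.32 ± 0.47 SE, limma adjusted p = 0.000333). Muc3, a membrane mucin, rose from 230 ± 78.5 to 1489 ± 408 (limma adjusted p = 0.00038). Of 31 peaks in WNT and colon stem cell genes 18 rose and 1 fell (median 1.90), with Prom1 giving 8 of the peaks and 7 of the rises. They included exon peaks of the kinase gene Csnk1a1 (2.73 ± 0.61, limma adjusted p = 0.00371), also 1 of the miRNA machinery genes, and Prom1 (1.90 ± 0.41, limma adjusted p = 0.00322). Apoptosis genes had 14 of 29 peaks higher and 1 lower (median 1.90), with a 3' UTR peak of Xiap, a caspase inhibitor, at 8.78 ± 7.69 and 130 ± 55.1 normalized reads, while Casp8 did not pass (-0.60). Cell cycle genes had 5 of 12 higher (median 1.57), among them cyclin D1, Ccnd1, at 2.36 ± 0.43 (limma adjusted p = 0.00132); Cdc25a was at -0.30.

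Of the 47 peaks in RAS-MAPK pathway and feedback genes 17 rose and 5 fell (median 1.04). The highest peak of Rps6ka3 fell by 1.70 (limma adjusted p = 0.0306), a call that ended without either of WT replicates 1 and 3 or without any one G12D replicate (adjusted p up to 0.162). Erbb2 was at 0.04 and did not pass. PI3K-AKT-MTOR genes had 8 of 32 peaks higher and 1 lower (median 0.91): the exon peak of Pik3r1, with miR-200 family sites, fell from 295 ± 116 to 66.0 ± 17.3 normalized reads (limma adjusted p = 0.00106), and Phlpp2 did not pass (0.91). TGF-beta and BMP genes had 6 of 18 higher and 1 lower (median 1.05); the Smad7 exon peak with a let-7 site fell by 1.55 (limma adjusted p = 0.00606), while 2 others of its 6 tested peaks rose, by 2.30 and 1.99. The highest Acvr1b peak did not pass (-1.25, limma adjusted p = 0.0504), and 2 others of its 7 rose, by 2.95 and 3.28. In the miRNA machinery 9 of 24 peaks rose and 0 fell (median 1.09), with the highest Tnrc6b peak at 0.03 and the other of its 2 higher. Classical let-7, miR-200 and miR-34 targets had 3 of 14 higher and 0 lower (median 0.72), with Met at -0.53 and the highest Cdc34 peak at 0.85, neither of which passed, while 2 other Cdc34 peaks rose, by 2.14 and 1.72. Adjusted over the list alone, the counts of higher and lower peaks were 17 and 5 for RAS-MAPK, 20 and 1 for WNT, 7 and 0 for machinery and 2 and 0 for classical targets. They were 4 and 0 for cell cycle, 8 and 1 for PI3K, 5 and 1 for TGF-beta, 15 and 1 for apoptosis, and 100 and 25 for colonocyte genes. For the RAS-MAPK list the median lay 0.01 below that of the other peaks while its mean and camera pointed up; for the PI3K and TGF-beta lists the mean lay above the others while camera and the median pointed down. Under quantile normalization the medians of the TGF-beta and classical target lists turned to -0.40 and -0.25.

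Peaks with a site for a given miRNA family did not move apart from the others past the threshold. camera called 0 of 25 seed sets, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.227. The 216 peaks with a miR-194 site had a median of 1.46 (101 higher and 16 lower; 104 and 17 adjusted over the list alone; camera unadjusted p = 0.018). Those with a miR-30, miR-148 or miR-25/92 site had medians of 0.26, 0.37 and 0.40, below the median of all peaks (unadjusted p = 0.0263, 0.0324 and 0.0364). The large let-7 set of 378 peaks had a median of 0.91, with 134 higher and 37 lower (131 and 37 adjusted over the list alone). For let-7 and miR-23 the median lay below that of the other peaks while the mean and camera pointed up, and for miR-22 the mean lay above while the median and camera pointed down. With 6-mer matches instead, miR-10 and miR-375 sets passed in the lower direction (adjusted p = 0.00138 and 0.0185; adjusted p = 0.999 for both with an estimated correlation).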

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

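Thinning, peaks called in both lists, 3' UTR peaks, leaving out both libraries numbered 2 and edgeR with the deposited factors were chosen after seeing the data. No miRNA or peak called in the main result changed sign under any alternative. The shallow WT pulldown libraries limit what can be said of peaks with few reads. The cause of the moves below was not tested. Leaving out libraries or features also changes the power, but the calls did not always fall. Without WT replicate 2 they rose to 56 miRNAs and 2275 peaks.

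The main result had 40 miRNAs changed (23 higher, 17 lower). A filter at a mean of 50 gave 24 (13 higher, 11 lower), of which 21 were among the 40, and no variance trend 18 (8 higher, 10 lower). With no filter 12 were higher. The same total per library gave 6 higher and 31 lower (median -0.26), edgeR with TMM 11 and 26 (median -0.13) and DESeq2 13 higher; with no filter the median was -0.10. Leaving out each library in turn gave 20 to 56 changed, 10 to 30 higher and 10 to 26 lower; the lowest count came without WT replicate 3. camera called 0 to 1 miRNA lists in those fits and 3 with no filter.

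The replicate number as a block gave 25 miRNAs (14 higher, 11 lower) and 2220 peaks. To look for pairing, each feature's group mean was subtracted and the deviations of same-numbered WT and G12D libraries were correlated. The correlations were -0.00, -0.42 and -0.32 for miRNAs and 0.04, -0.04 and -0.01 for peaks. They gave no sign of pairing. With 3 libraries per group the deviations constrain each other, so pairing could not be excluded.

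The main result had 2170 peaks changed. A filter at a mean of 20 gave 790 (429 higher, 361 lower; median 0.13), of which 775 were among the 2170, and peaks called in both lists gave 312 (105 higher, 207 lower; median -0.45). No filter gave 2469 higher (median 1.47), quantile normalization 873 higher (0.16), edgeR with TMM 894 lower (0.47), DESeq2 a median of 0.66 and a pseudocount of 5 one of 0.69. Leaving out each library in turn gave 1410 to 2275 changed and 977 to 1632 higher; the count fell by over 1.5 times without G12D replicate 2, and that of higher peaks also without G12D replicate 3. Peaks at or above the median score overlapped in 68.5% of the WT list. With the calls of the authors' deposited table the odds ratio of higher peaks for 3' UTRs was 0.823. camera called 1 seed set among 3' UTR peaks and 2 with 6-mer sites.

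Named features that changed sign were none of those called. With the same total per library these were miR-200c-3p (-0.11), miR-30e-5p (-0.11), let-7i-5p (-0.0591), miR-16-5p (-0.29), miR-15a-5p (-0.0209), miR-30a-5p (-0.10), miR-26b-5p (-0.24), miR-133a-3p (-0.23) and miR-375-3p (-0.0131). With quantile normalization they were miR-200c-3p (-0.29), miR-30e-5p (-0.20), let-7i-5p (-0.0714), miR-16-5p (-0.0674), miR-30a-5p (-0.0564), miR-26b-5p (-0.0399) and Actb (0.48). TMM turned miR-16-5p (-0.15), miR-26b-5p (-0.0876), miR-133a-3p (-0.34), Erbb2 (-0.45) and Tnrc6b (-0.58). DESeq2 turned miR-16-5p (-0.00875), miR-133a-3p (-0.18), Erbb2 (-0.25) and Tnrc6b (-0.37), and edgeR with the deposited factors miR-133a-3p (-0.13) and Tnrc6b (-0.0479). Thinning turned Erbb2 (-0.11) and Cdc25a (0.0928), and leaving out both libraries numbered 2 Tnrc6b (-0.0760) and Phlpp2 (-0.25). Over the fits without 1 library the ranges were -0.19 to 0.15 for let-7b-5p, -0.33 to 0.0245 for miR-34a-5p, -0.10 to 0.26 for miR-16-5p, -0.17 to 0.31 for miR-26b-5p, -0.30 to 0.75 for miR-133a-3p, -0.44 to 0.58 for miR-143-3p, -0.30 to 0.25 for Erbb2 and -0.12 to 0.33 for Tnrc6b.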

Other observations

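The tests of peaks called in both lists, of the scaling of peaks, of the ratio of peaks without sites and of the miR-30 strata, and the splits of miRNA and peak counts, were chosen only after the results were seen.

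Most tested peaks lay higher in G12D, at a median of 1.05. Selection of peaks in the deeper G12D libraries may contribute but stays open: peaks called in both lists had a median of -0.45, but a call in the shallow WT list keeps peaks high in WT, so a low median there decides nothing. Unequal depth acting on the log2 values alone is unlikely to be the whole cause. Thinning every library to the shallowest left the median at 1.05 or above in 20 draws. Thinning kept the peaks already called, so it could not test how depth affects which peaks were called. Among peaks with a mean of at least 20 the median was 0.13, so the shift was smaller there. Whether this reflects read level or the list a peak was called in was not tested. Scaling also stays open: the median was 1.23 with the same total per library, 0.66 with DESeq2, 0.474 with TMM and 0.16 with quantile normalization. Whether the genotype itself adds Ago2 sites could not be separated from selection and scaling.

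The 38 snRNA and 5S rRNA peaks had a median of -4.54, and 37 of them were lower in G12D. More unspecific RNA of every kind in the WT pulldown could produce this, but reads in peaks without a site stood at a ratio of 1.18 of G12D to WT, and the list sets that ratio: 0.951 in both lists, 0.117 in the WT list and 3.76 in the G12D list. That test was first read as excluding the explanation and then as open. Selection in the WT list could also add to it, but only 2 of these peaks were called in the G12D list, at a median of -0.88. No biological explanation was tested.

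Peaks might be thought to follow the abundance of their miRNA family, but across 25 seed families the Spearman correlation of the changes was 0.0269 (permutation p = 0.899; Pearson 0.130, permutation p = 0.541), which decides nothing. Without the 2 farthest families these were -0.0978 and -0.0104, and 4 such relations were computed. Among 3' UTR peaks the 57 with a miR-30 site had a median of -0.15 against 1.25 for the others (adjusted p = 0.000647; adjusted p = 0.754 with an estimated correlation). Of these 38.6% were in both lists, 49.1% in the G12D list and 12.3% in the WT list, against 17.8%, 78.4% and 3.81% of the others. Within both lists their median was -0.90 against -0.27, within the WT list -2.85 against -2.22, and within the G12D list 1.59 against 1.62; the change itself helps to decide the list, so this split decides nothing.

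With 3 libraries against 3 there are 10 ways to split them, so no share under 0.05 is possible. The real split gave 40 miRNAs and the highest other 0, so 1 split reached the real count; for peaks 1 split did, with 2170 against 0. For miRNA lists all 10 splits reached the real count of 0, with 3 the highest other, and for gene lists and seed sets all 10 did, with 0 the highest other.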
